A study of Mus musculus with 6 samples.

How the data were processed

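Gene expression was measured on 6 Affymetrix arrays, 1 per sample, from mouse fibrosarcoma cells of C57BL/6 background that carry the Q72L form of Rras2, a RAS-related GTPase. The cells had been transduced with the empty lentiviral vector pLKO (controls, replicates 1 to 3 as numbered in the labels) or with a vector for an shRNA against Rras2 (knockdown, replicates 4 to 6). Only 1 such shRNA was used, so effects on other targets cannot be separated from the loss of Rras2. Per the labels, total RNA was isolated with Trizol and turned into biotin-labelled cRNA. The deposited values are log2 signals per probe set made with RMA, in R 3.6.3, per the submitters' processing notes. RMA corrects background, quantile normalizes the arrays and summarizes the probes of a set. The version of the RMA package and any filter are not given in the sources used here. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The controls are numbered 1 to 3 and the knockdown samples 4 to 6, no scan dates were at hand, and any batch that follows these numbers cannot be told apart from the group.

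The table holds 29129 probe sets, of which 6923 are control probe sets. The platform annotation used here gave 1 gene symbol to 19572 probe sets, several symbols to 0, and none to 2634 of the 22206 transcript probe sets. All 19572 Entrez identifiers were found in the RefSeq gene table of GRCm38.p6, and 0 symbols needed updating. That table served only for names, and no coordinates are given because the build behind the array annotation is not stated. For 55 genes with more than 1 probe set, the one with the highest mean over the 6 arrays was kept, which left 19505 genes. Some genes of interest, among them Hras and Ccnd1, were not analysed here. No detection calls come with the values. The 5222 negative-control probe sets had a median log2 signal of 5.02 and a 95th percentile of 7.92 over the 6 arrays, and 8131 genes had a mean above that percentile. Signals in this low range are compressed, so log2 differences of dim genes can understate a change. The number of arrays limits the precision, and the median SE of a log2 difference was 0.096.

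Knockdown and control arrays were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over all 19505 genes and a threshold of 0.05 on the adjusted p. The residual degrees of freedom were 4 and the prior degrees of freedom 4.85. Log2 differences are knockdown minus control, and errors on them are SEs from limma. Group levels are means ± SD over 3 arrays. For Rras2 an exact two-sided permutation test was added; with 3 arrays against 3 its smallest possible p is 0.1. Gene lists were tested with limma's camera, which compares the genes of a list with all other genes, at its preset correlation of 0.01, with adjustment over 43 lists. The lists were tested again with a correlation estimated from the data and with fry, which asks whether the genes of a list move on balance one way. The 43 lists hold 1316 entries and were fixed before the data were examined, as were the tests and the other settings listed below. Of these entries 1200 were measured, 13 of them through an older or newer name of the same gene. A listed name that is itself the current symbol of another gene was never matched as a synonym.

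The genes named in the text follow a rule fixed at the same time. It takes Rras2 and its relatives, and the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap and whose brighter group lay above the median of all genes, leaving out predicted and unnamed genes. For each list past its threshold, or with 3 or more members past the gene threshold, it takes up to 4 members with the largest changes and up to 2 more that went the other way. It also takes a set of genes whatever their values, among them Dusp6, Spry4, Etv4, Fosl1, Ccnd1, Myc, Cdkn1a, Cdkn1b, Mki67, Irs2, Col1a1, Mmp3, Ccl2 and Isg15. Genes outside the rule are said to be so where they appear.

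The alternatives were a second quantile normalization, centring on each array's median, cyclic loess, leaving out the 30% of genes with the lowest mean, testing every transcript probe set, averaging the probe sets of a gene, eBayes with a trend and robust settings, array weights, a Welch test per gene, a minimum fold of 1.2 with treat, camera on ranks, and leaving out each array in turn. The method was tested on simulated data for the comparison of knockdown and control, with the real genes' means and residual SDs and 200 genes of 19505 changed by known amounts. It recovered 24 of 66 genes changed by 0.5 on the log2 scale, 64 of 67 changed by 1 and 67 of 67 changed by 2, and called 3 of 19305 unchanged genes. The adjusted threshold depends on how many genes change, so these rates hold for 200 changed genes and can differ in the real comparison. A list raised by 0.5 was recovered, and 0 of 39 lists that share no gene with it were called. The simulated noise was drawn separately for each gene, so these list results do not apply to lists whose genes vary together.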

Results

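Expression profiles were compared between Rras2(Q72L) fibrosarcoma cells with the empty vector and the same cells with an shRNA against Rras2. The comparison asks which transcripts differ when Rras2 RNA is lowered in tumor cells that carry the mutant form. Fibrosarcoma is a malignant tumor of fibroblast-like cells. Each group had 3 arrays, and 19505 genes were tested on the log2 RMA scale. The median gene signal lay between 7.22 and 7.28 on the 6 arrays. Pearson correlations across genes, which are not independent replicates, were 0.9941 to 0.9966 within a group and 0.9884 to 0.9931 between groups. The first principal component held 51.9% of the variance and had scores of -21.1 to -12.9 for the controls and 8.30 to 22.7 for the knockdown arrays, with knockdown replicate 5 nearest the controls. No pair of arrays shared more than 7 identical values among the 29129 probe sets.

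Rras2 itself, measured by the probe set TC0700004132.mm.2, was 10.74 ± 0.08 in the controls and 9.33 ± 0.32 in the knockdown (SD, n = 3 each). Its log2 difference was -1.41 ± 0.14 (SE; limma adjusted p = 0.00163), and all 3 knockdown arrays lay below all 3 controls. The exact permutation test gave p = 0.1, the smallest it can give with 3 arrays against 3. On the linear scale 37.6% of the control signal remained (95% interval 29.9 to 47.2%), with 31.8% on replicate 4, 48.1% on replicate 5 and 34.6% on replicate 6. Its close relatives Rras, Mras and Nras had log2 differences of 0.09 ± 0.10, 0.12 ± 0.08 and -0.09 ± 0.08, and none passed the threshold (limma adjusted p = 0.703, 0.489 and 0.612). Of the 16 measured members of the RAS family list, Rras2 fell and Rerg, outside the naming rule, rose by 0.72 and stayed in 2 of the 6 fits without 1 array. The list as a whole did not pass (median -0.08, adjusted over the list alone 1 higher and 1 lower, camera adjusted p = 0.425).

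In all, 1017 genes (5.21%) passed the threshold, 584 of them higher and 433 lower in the knockdown. Of these, 135 differed at least 2-fold, 114 higher and 21 lower. The groups did not overlap for 25.5% of genes, against 10% by chance for 3 arrays against 3. The count was 463, 589 and 427 without control replicates 1, 2 and 3, and 392, 1136 and 431 without knockdown replicates 4, 5 and 6, and 325 genes stayed past the threshold in all 6 of these fits. When each array was centred on its median, 506 genes were higher and 567 lower. In the main fit, 3733 of the 19505 genes had an unadjusted p under 0.05 in limma. Counts of such genes within a list are to be read against that share. Of the genes named below as risen or fallen, Myoz2, Dram1, Pdk1, Wnt9a, Sema3d, Itga11, Twist2 and Pparg had both group means below the 95th percentile of the negative controls, as had Rerg, so the sizes of their changes are imprecise. The same holds where the dimmer group alone lay below it, as for the rises of Myog, Perp, Bcl2l11, Ppargc1a, Thbs3, Adamts5, Mmp19, Fgf7, Nkd2, Epha3, Sema3f and Arhgef17 and the falls of Rrp12, Serpinb2, Apln, Apcdd1 and Sema5a.

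Of the 10 largest rises, 7 were in genes of skeletal muscle fibers and their formation. Myl1, a fast-muscle myosin light chain, rose from 6.89 ± 0.42 to 10.74 ± 0.43 (SD, n = 3 each), 14.5-fold. Myh3, the embryonic myosin heavy chain, rose 12.2-fold and Myh8, the perinatal form, 7.93-fold. Mymk, which encodes a membrane protein of myoblast fusion, rose 8.02-fold, the light chain gene Mylpf 8.51-fold, the skeletal actin gene Acta1 6.86-fold and the Z-disc gene Myoz2 6.25-fold. These 7 genes had limma adjusted p-values between 0.000223 and 0.00174, and their control means lay below the 95th percentile of the negative controls. The other 3 of the 10 largest rises were Chrdl1, a secreted BMP antagonist (10.5-fold), Islr, an immunoglobulin-superfamily gene with leucine-rich repeats (6.56-fold), and the matrix proteoglycan gene Fmod (5.83-fold). The control means of Chrdl1 and Fmod lay below that percentile too, so the folds and order of all but Islr are imprecise.

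Of the 21 measured skeletal muscle markers, 11 rose, 0 fell and 10 did not pass (median 0.68, camera adjusted p = 1.18e-14, adjusted p = 0.156 with an estimated correlation). Adjusted over the list alone, 14 rose and 1 fell. The myogenic regulator Myog, outside the naming rule, rose by 1.07 and stayed in 5 of the 6 fits without 1 array (limma adjusted p up to 0.0534). Also outside it, Myod1 (0.68 ± 0.18, adjusted p = 0.0743), Pax7 (0.01 ± 0.08), Pax3 (0.06 ± 0.08), Ckm (0.15 ± 0.14) and Ttn (0.21 ± 0.11) did not pass. Myod1, Ckm and Ttn lay below the 95th percentile of the negative controls in both groups, so a change in them could be missed. The list's median deviation from the 6-array mean was 0.16 on knockdown replicate 5, against 0.52 and 0.54 on replicates 4 and 6, and 9 of the 11 calls stayed without any 1 array.

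**Figure D1:**
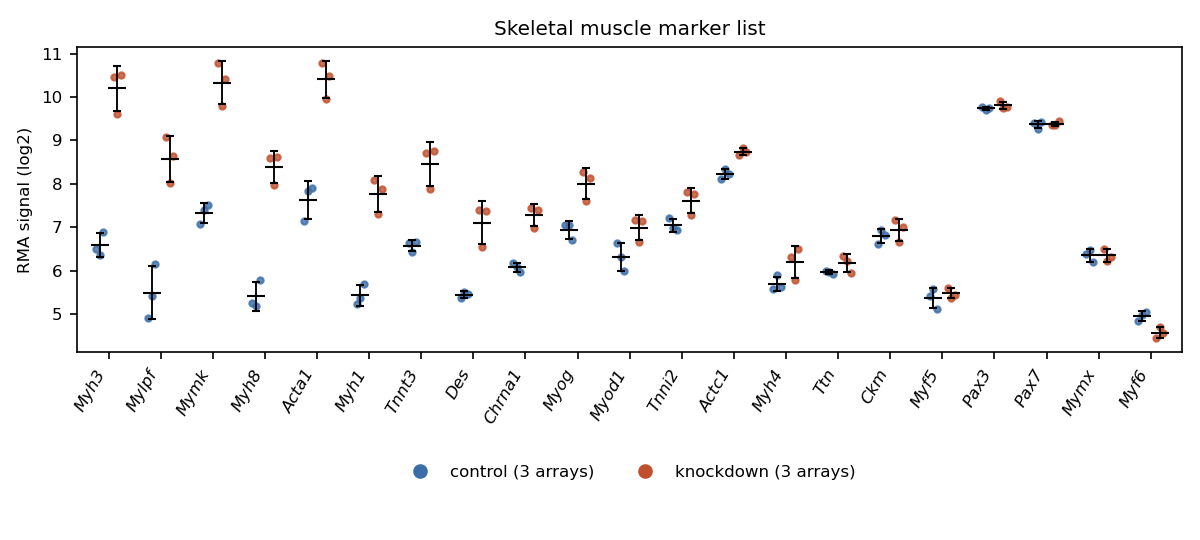
Log2 RMA signal (vertical axis) of the 21 measured skeletal muscle markers (horizontal axis, sorted by log2 difference) on the 3 control and 3 knockdown arrays; points are arrays, and bars are group means with SD. Myh3 is near 6.59 in the controls and 10.20 in the knockdown, while Pax7 and Pax3 differ by 0.01 and 0.06.

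Genes whose transcripts are known to follow ERK signalling were tested as the ERK output list. Of 26 measured genes of the ERK output list, 10 fell, 1 rose and 15 did not pass (median -0.30, camera adjusted p = 4.23e-06, adjusted p = 0.191 with an estimated correlation). Adjusted over the list alone, 12 fell and 2 rose. Etv5 fell from 9.58 ± 0.15 to 8.48 ± 0.13 (SD, n = 3 each), and the related ETS factors Etv4 and Etv1 fell by 0.81 and 0.78 on the log2 scale. The MAP kinase phosphatases Dusp4 and Dusp6 fell by 0.78 and 0.58, the feedback inhibitor Spry4 by 0.57 and the AP-1 gene Fosl1 by 0.67. The ephrin receptor gene Epha4 went the other way, with a rise of 0.62. Of these 11 calls 4 stayed in every fit without 1 array, the falls of Etv5, Etv1 and Dusp4 and the rise of Epha4. Dusp6 stayed in 5 of the 6 fits, Etv4 in 3, and Spry4 and Fosl1 in 1 each. The number of lower members ranged from 3 without control replicate 3 to 10 without knockdown replicate 5. Myc, another target of growth signalling, had a log2 difference of -0.34 ± 0.12 and did not pass (adjusted p = 0.161).

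**Figure D2:**
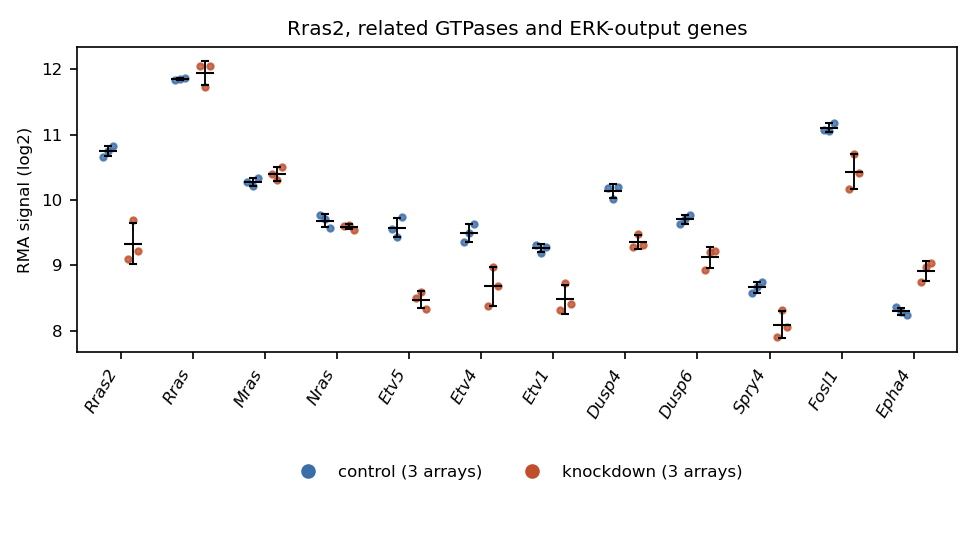
Log2 RMA signal (vertical axis) of Rras2, 3 related GTPases and 8 genes of the ERK output list (horizontal axis) on the 3 control and 3 knockdown arrays; points are arrays, and bars are group means with SD. Rras2 lies at 10.74 in the controls and 9.33 in the knockdown, Etv5 at 9.58 and 8.48, and Epha4 alone of the 8 ERK genes is higher in the knockdown.

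Components of the RAS-ERK and PI3K pathways did not shift as a list (37 measured, median 0.00217, adjusted over the list alone 3 higher and 1 lower, camera adjusted p = 0.79). Pik3r1, a regulatory subunit of PI3K, rose by 0.63 and the receptor gene Pdgfrb by 0.37, while Map2k1, which encodes the kinase MEK1, fell by 0.35. Without 1 array, Pik3r1 passed in all 6 fits, Pdgfrb in 1 (adjusted p up to 0.166) and Map2k1 in 0. Among 28 immediate early genes 3 rose, Egr2 by 0.61, Jund by 0.53 and Dusp1 by 0.43, and 0 fell (median -0.00, adjusted over the list alone 5 higher and 1 lower, camera adjusted p = 0.214); none of the 3 stayed in every fit without 1 array. In the FOXO target list 5 of 24 genes rose and 0 fell (median 0.17, adjusted over the list alone 5 higher and 0 lower, camera adjusted p = 0.000787, adjusted p = 0.156 with an estimated correlation). Pik3ip1, an inhibitor of PI3K, rose 2.84-fold, while Ccng2, Sesn1 and Gadd45a rose by 0.58, 0.58 and 0.50 on the log2 scale; 3 of these 5 calls stayed in every fit without 1 array, and that of Gadd45a in 2 of the 6. Irs2 differed by 0.14 ± 0.10 and did not pass.

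The ribosome biogenesis and MYC target list had the lowest median of the 43 lists. Of 41 measured genes 10 fell, 0 rose and 31 did not pass (median -0.31, camera adjusted p = 6.65e-15, adjusted p = 0.191 with an estimated correlation), and 24 fell when adjusted over the list alone. Rrp12 fell by 0.77, Dkc1 by 0.70, Polr1a, the largest subunit of RNA polymerase I, by 0.54 and Tcof1 by 0.50. None of these 10 calls stayed in every fit without 1 array. Among 45 cytosolic ribosomal protein genes 0 passed limma's threshold, 0 when adjusted over the list alone, and 9 had an unadjusted p under 0.05, with a median of -0.13 (camera adjusted p = 3.57e-06, adjusted p = 0.287 with an estimated correlation).

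Of 42 S phase and E2F target genes 1 fell, the replication helicase gene Mcm6, by 0.79 (list median -0.16, adjusted over the list alone 0 higher and 1 lower, camera adjusted p = 1.63e-06, adjusted p = 0.191 with an estimated correlation). The mitosis list had 1 rise and 1 fall among 51 genes, Nusap1 and Ccna2, both outside the naming rule, and did not pass (median 0.04, adjusted over the list alone 1 higher and 0 lower, camera adjusted p = 0.0654). Nusap1 passed in all 6 fits without 1 array and Ccna2 in 1 (adjusted p up to 0.157). The proliferation marker Mki67 differed by 0.04 ± 0.08. The CDK inhibitors Cdkn1a and Cdkn1b differed by 0.20 ± 0.09 and 0.22 ± 0.08 and did not pass (adjusted p = 0.28 and 0.182). Their list, with the D cyclins, had 0 of 14 genes past limma's threshold, 4 with an unadjusted p under 0.05 and, adjusted over the list alone, 0 higher and 1 lower (median 0.10, camera adjusted p = 0.0532). Among 32 p53 targets 5 rose and 0 fell (median 0.09, adjusted over the list alone 9 higher and 2 lower, camera adjusted p = 0.00136, adjusted p = 0.191 with an estimated correlation), among them Perp by 1.51, Sulf2 by 0.84 and Dram1 by 0.66; 4 of these 5 calls stayed in every fit without 1 array. The apoptosis regulators had 1 rise and 1 fall among 27 genes, Bcl2l11 and Bcl2, both outside the naming rule (median 0.07, adjusted over the list alone 1 higher and 2 lower, camera adjusted p = 0.225), and they passed in 2 and 1 of the 6 fits without 1 array (adjusted p up to 0.0894 and 0.147).

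Several lists cover metabolism and stress. Of 21 glycolysis genes 4 fell and 0 rose: Pfkl by 0.58, Pdk1 by 0.52, and the transporter genes Slc16a1 and Slc2a1 by 0.41 and 0.38 (median -0.15, adjusted over the list alone 1 higher and 7 lower, camera adjusted p = 0.00112, adjusted p = 0.156 with an estimated correlation). None of these 4 stayed in every fit without 1 array. The hypoxia list, which shares Pdk1 and Slc2a1, had 3 falls among 25 genes, with Egln3 the largest at -0.95, and did not pass (median -0.05, adjusted over the list alone 2 higher and 4 lower, camera adjusted p = 0.451); of its 3 calls that of Egln3 stayed in every fit without 1 array. Among 20 cholesterol synthesis genes Lss fell by 0.43 (median -0.18, adjusted over the list alone 1 higher and 8 lower, camera adjusted p = 0.00643, adjusted p = 0.2 with an estimated correlation), and among 15 fatty acid synthesis genes Elovl6 fell by 0.72 (median -0.12, adjusted over the list alone 0 higher and 2 lower, camera adjusted p = 0.0256, adjusted p = 0.191 with an estimated correlation). Lss and Elovl6 each stayed in 1 of the 6 fits without 1 array (adjusted p up to 0.134 and 0.0899). The second of these list calls was lost without knockdown replicate 6 (camera adjusted p = 0.0816). Of 33 ATF4 and amino acid stress genes 4 fell, Slc1a5 by 0.59, Psat1 by 0.56, Eif4ebp1 by 0.43 and Shmt2 by 0.43, and the list did not pass (median -0.04, adjusted over the list alone 1 higher and 6 lower, camera adjusted p = 0.0951). Psat1 stayed in every fit without 1 array, and Slc1a5, Eif4ebp1 and Shmt2 each in 1 of the 6 (adjusted p up to 0.121, 0.0837 and 0.0986). The oxidative phosphorylation list (1 of 50 rose, Ppargc1a, outside the naming rule, and 1 when adjusted over the list alone; median -0.03, camera adjusted p = 0.127) and the NRF2 list (1 of 23 rose, Gstm2, outside the naming rule, and adjusted over the list alone 1 higher and 3 lower; camera adjusted p = 0.469) did not pass. The median of the NRF2 list was -0.13 although its called member rose, and Gstm2 passed in 2 of the 6 fits without 1 array. Nor did the unfolded protein response list, with 0 of 22 genes past limma's threshold, 3 with an unadjusted p under 0.05, 0 when adjusted over the list alone, a median of 0.02, a mean of -0.01 and a camera adjusted p of 0.996. In the lysosome and autophagy list Npc2 rose by 0.48 and Hexa by 0.41 among 45 genes (median 0.11, adjusted over the list alone 3 higher and 1 lower, camera adjusted p = 0.00681, adjusted p = 0.272 with an estimated correlation); without control replicate 2 the list did not pass (camera adjusted p = 0.0735). Npc2 stayed in 5 and Hexa in 1 of the 6 fits without 1 array.

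The matrix around the cells was covered by 2 lists. Of 51 collagens and matrix proteins 15 rose, 0 fell and 36 did not pass (median 0.18, adjusted over the list alone 19 higher and 1 lower, camera adjusted p = 4.14e-07, adjusted p = 0.156 with an estimated correlation). Of these 15 calls 7 stayed in every fit without 1 array. Besides Fmod, the largest rises were in Postn (4.06-fold), Thbs3 (2.88-fold) and Col6a2 (2.34-fold), and Col1a1 differed by 0.24 ± 0.10 and did not pass (adjusted p = 0.248). The matrix remodelling list had 8 rises and 2 falls among 32 genes (median 0.11, adjusted over the list alone 10 higher and 2 lower, camera adjusted p = 0.000217, adjusted p = 0.199 with an estimated correlation). The proteoglycan-cleaving Adamts5 and Adamts4 rose 3.53-fold and 2.46-fold and Mmp19 rose 2.72-fold, while Serpinb2 and Plaur, both of the plasminogen activator system, fell by 1.43 and 0.47. Of these 10 calls 6 stayed in every fit without 1 array. The fall of Serpinb2 had an adjusted p of 0.0479 and stayed in 1 of the 6 fits without 1 array, where its adjusted p reached up to 0.149. Mmp3 was at background in both groups (4.72 ± 0.19 and 4.77 ± 0.11).

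Lists of signalling genes and secreted factors were tested next. Of 28 TGF-beta and BMP target or ligand genes 9 rose and 0 fell (median 0.32, adjusted over the list alone 15 higher and 1 lower, camera adjusted p = 7.57e-10, adjusted p = 0.133 with an estimated correlation), with Tgfb2 up by 0.75, Tgfb3 by 0.66, Tgfbi by 0.65 and Bmp4 by 0.58; 2 of these 9 calls stayed in every fit without 1 array. The list of angiogenic factors had 9 rises and 2 falls among 26 genes (median 0.18, adjusted over the list alone 11 higher and 2 lower, camera adjusted p = 0.000135, adjusted p = 0.156 with an estimated correlation). Its largest changes were rises of the growth factor genes Igf1 (3.64-fold), Igf2 (3.01-fold) and Fgf7 (2.18-fold), and Apln and Bdnf fell by 1.07 and 0.46; 6 of these 11 calls stayed in every fit without 1 array. In the WNT list 4 genes rose and 1 fell among 30 (median 0.09, adjusted over the list alone 10 higher and 3 lower, camera adjusted p = 0.00681, adjusted p = 0.213 with an estimated correlation). The WNT inhibitor gene Nkd2 rose 4.28-fold, Fzd1 1.62-fold and Wnt9a 1.37-fold, and the inhibitor Apcdd1 fell by 1.61. Of these 5 calls 3 stayed in every fit without 1 array, and that of Wnt9a stayed in 1 of the 6. Among 34 chemokines and cytokines Il6 rose by 0.87, Il18 by 0.54 and Csf2 by 0.40, all from levels below the 95th percentile of the negative controls, and Ccl9 fell by 0.48 (median 0.02, adjusted over the list alone 3 higher and 2 lower, camera adjusted p = 0.425). None of these 4 calls stayed in every fit without 1 array, with Il18 and Csf2 past in 1, Il6 in 2 and Ccl9 in 3 of the 6. Ccl2 was 8.56 ± 0.10 in the controls and 8.56 ± 0.19 in the knockdown.

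Guidance and adhesion were covered by further lists. Of 44 semaphorin, plexin and ephrin genes 10 rose and 1 fell (median 0.12, adjusted over the list alone 12 higher and 1 lower, camera adjusted p = 0.000405, adjusted p = 0.156 with an estimated correlation). Epha3 rose 2.75-fold, Epha7 1.83-fold, Sema3d 1.75-fold and Sema3f 1.69-fold, and Sema5a fell by 0.53; 3 of these 11 calls stayed in every fit without 1 array. Among 32 integrins and adhesion receptors 5 fell and 2 rose, with no shift of the list (median -0.01, adjusted over the list alone 6 higher and 7 lower, camera adjusted p = 0.996). Itga6, the laminin-binding integrin subunit, fell by 1.09, Alcam by 0.81 and Sdc4 by 0.62, while Itga11, a collagen-binding subunit, rose by 0.85 and Cdh11 by 0.42. Of these 7 calls 4 stayed in every fit without 1 array, and the rises of Itga11 and Cdh11 stayed in 2 and 1 of the 6 (adjusted p up to 0.0807 and 0.129). Genes of the SRF and YAP list rose in 4 cases and fell in 0 of 31 (median 0.16, adjusted over the list alone 13 higher and 2 lower, camera adjusted p = 2.31e-05, adjusted p = 0.156 with an estimated correlation), with F3 up 2.34-fold, Ajuba 1.40-fold, Arhgef17 1.31-fold and Crim1 1.31-fold. Crim1 passed in 0 (adjusted p = 0.0838 to 0.127) and Arhgef17 in 1 of the 6 fits without 1 array.

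**Figure D3:**
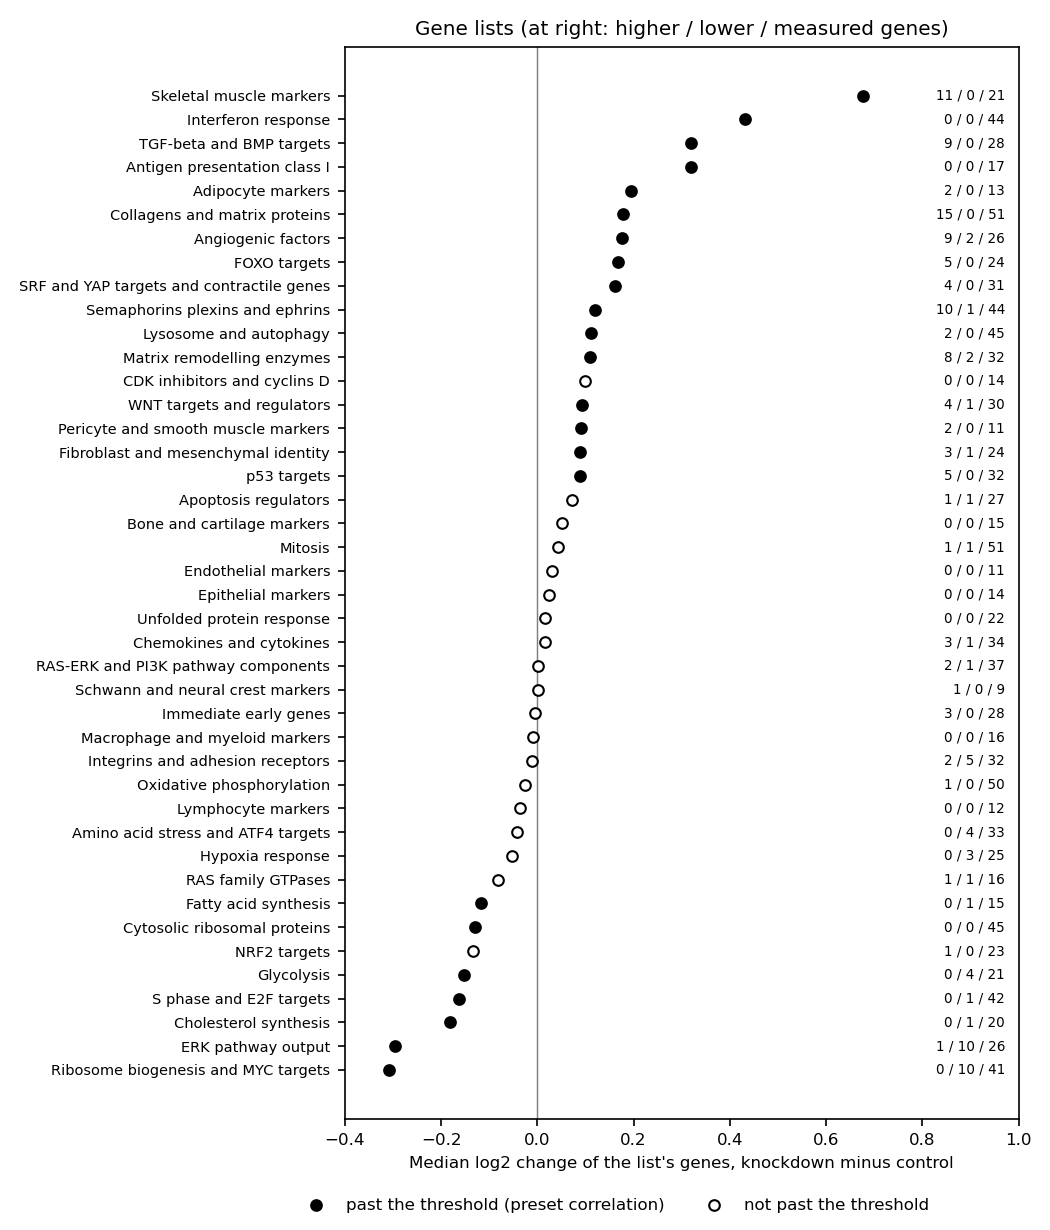
Median log2 difference, knockdown minus control (horizontal axis), of the measured genes of 42 lists (vertical axis; 1 of the 43 lists tested is not shown or described here); filled points are lists past the camera threshold at the preset correlation, and the figures at the right give genes higher, lower and measured. Skeletal muscle markers lie at 0.68, and the ribosome biogenesis list at -0.31.

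Among genes whose groups did not overlap and whose brighter group lay above the median signal of all genes, the 10 largest falls were in Rras2, Serpinb2, Apcdd1, Prl2c2 and Prl2c3 (-1.84 ± 0.30 and -1.57 ± 0.23), Nefm (-1.76 ± 0.27), Slc14a1 (-1.70 ± 0.20), Kcnb2 (-1.61 ± 0.16), Esm1 (-1.56 ± 0.13) and Ccbe1 (-1.36 ± 0.19; errors are SEs). Prl2c2 and Prl2c3 encode proliferins, near-identical paralogs, so their separate values are uncertain. Nefm encodes a neurofilament subunit, Slc14a1 a urea transporter and Kcnb2 a potassium channel subunit, and Esm1 and Ccbe1 encode secreted proteins linked to vessels. In the fits without 1 array, Prl2c2 passed in 5 of the 6 (limma adjusted p up to 0.0516), and Prl2c3, Nefm, Slc14a1, Kcnb2, Esm1 and Ccbe1 in all 6. Over all 6 arrays, the limma adjusted p-values of these 7 lay between 0.000799 and 0.0109. Except for Slc14a1, their knockdown means lay below the 95th percentile of the negative controls, for Kcnb2 the control mean too, so these log2 differences are imprecise in size.

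Interferon-response genes differed more between arrays of one group than other genes did, with a median within-group SD of 0.53 against 0.12 for all genes. Of 44 interferon-response genes 0 passed limma's threshold, 0 when adjusted over the list alone. An unadjusted p under 0.05 in limma was found for 8 of them, against 3733 of all 19505 genes. The list nevertheless had a median of 0.43 and a camera adjusted p of 0.000491 (adjusted p = 0.629 with an estimated correlation). Of 17 class I antigen presentation genes 0 passed over all genes, 8 had an unadjusted p under 0.05, and 6 rose when adjusted over the list alone (median 0.32, camera adjusted p = 4.73e-05, adjusted p = 0.425 with an estimated correlation). Isg15, an interferon-induced ubiquitin-like protein, was 7.25 ± 0.78 in the controls and 7.84 ± 1.19 in the knockdown. The median deviation of the interferon list from its 6-array mean was -0.02, 0.07 and -0.66 on control replicates 1, 2 and 3, and 0.63, -0.47 and 0.51 on knockdown replicates 4, 5 and 6. Without knockdown replicate 5, 14 interferon and 9 class I genes rose, and without control replicate 3 or knockdown replicate 4 the interferon list did not pass (camera adjusted p = 0.156 and 0.122).

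**Figure D4:**
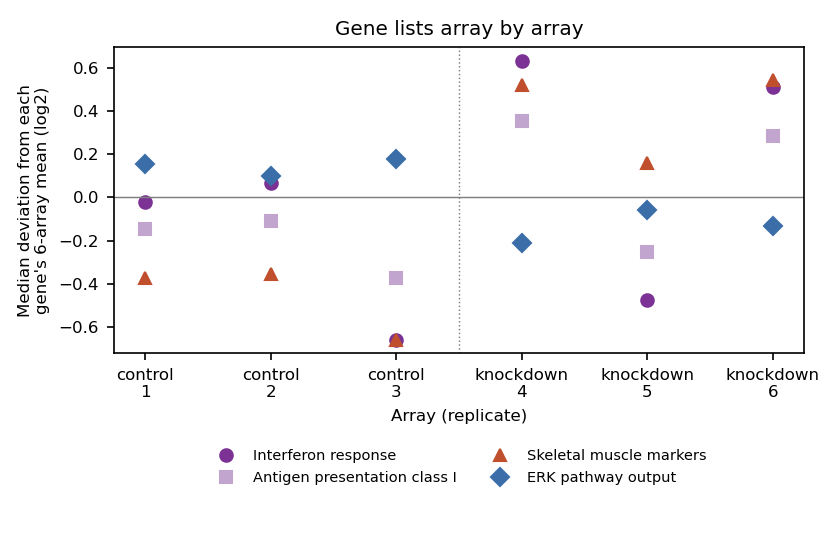
Median over each list of the gene's deviation from its own 6-array mean (vertical axis, log2) on each array (horizontal axis), for 4 lists. The interferon list lies at -0.66 on control replicate 3 and at -0.47 on knockdown replicate 5, while the ERK output list is above 0 on all controls and below 0 on all knockdown arrays.

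In the fibroblast and mesenchymal list 3 genes rose and 1 fell among 24 (median 0.09, adjusted over the list alone 5 higher and 2 lower, camera adjusted p = 0.0346, adjusted p = 0.191 with an estimated correlation). Ebf1 rose by 0.52, Zeb1 by 0.44 and Pdgfrb by 0.37, and Twist2 fell by 0.70; the list did not pass without control replicate 3 or knockdown replicate 4 (camera adjusted p = 0.109 and 0.104) or by camera on ranks (0.0581). Ebf1 and Twist2 stayed in every fit without 1 array, Zeb1 in 2 and Pdgfrb in 1 of the 6. The pericyte and smooth muscle markers had 2 rises among 11 genes, Des, which is also a muscle marker, and Notch3, which stayed in 1 of the 6 fits without 1 array. Both group means of each lay below the 95th percentile of the negative controls. Their median was 0.09 with a camera adjusted p of 0.0286, adjusted p = 0.286 with an estimated correlation, 0.122 without knockdown replicate 4 and 0.0745 on ranks. Adjusted over the list alone, 3 rose and 0 fell. The adipocyte markers had 2 rises among 13 genes, Pparg by 0.68 and Plin2, past in 1 of the 6 fits without 1 array, by 0.37 (median 0.19, adjusted over the list alone 4 higher and 1 lower, camera adjusted p = 0.00935, adjusted p = 0.187 with an estimated correlation). That list did not pass without control replicate 3 and knockdown replicate 5 together, a fit chosen after seeing the data (camera adjusted p = 0.0909).

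The other marker lists did not pass. The Schwann and neural crest markers had 1 rise among 9 genes, Egr2, which stayed in 3 of the 6 fits without 1 array (median 0.000918, adjusted over the list alone 2 higher and 0 lower, camera adjusted p = 0.493). No gene passed limma's threshold among 16 macrophage and myeloid markers (median -0.01, 3 with an unadjusted p under 0.05, camera adjusted p = 0.791), 12 lymphocyte markers (-0.04, 0 and 0.858), 11 endothelial markers (0.03, 4 and 0.703), 14 epithelial markers (0.03, 1 and 0.837) or 15 bone and cartilage markers (0.05, 1 and 0.127). The median signals of these lists, from 5.01 for macrophage and myeloid to 6.45 for Schwann and neural crest markers, lay below the 7.25 of all genes. Median signals were 6.90 for skeletal muscle, 7.11 for pericyte and smooth muscle and 6.15 for adipocyte markers. The epithelial list had a median above 0 but a mean of -0.01 and a camera test pointing down. Adjusted over the list alone, 2 endothelial markers were higher and 2 lower, 1 macrophage and myeloid marker was lower, and 0 passed in the lymphocyte, epithelial and bone lists. The immediate early list had a median of -0.00472 and a mean of 0.07 with a test pointing up, and the integrin list a mean of -0.02 with a test pointing up. The median and mean of the unfolded protein response list differed in sign too.

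In total 24 of the 43 lists passed, 17 of them up and 7 down. With an estimated correlation 0 passed, with 9 at an unadjusted p under 0.05, and by fry 26 passed, among them 21 of the 24. The 3 not called by fry were the interferon, class I and pericyte lists (fry adjusted p = 0.588, 0.29 and 0.06). Another 5 lists passed fry but not camera: the RAS family (fry adjusted p = 0.0131), hypoxia (0.0202), ATF4 and amino acid stress (0.0131) and oxidative phosphorylation (0.013) lists, lower, and the CDK inhibitor list (0.0111), higher. Fry does not compare a list with other genes. The RAS family list includes Rras2, the target of the shRNA, so the lower result of that list is in part built in.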

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

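No test in this part was chosen after its result was seen. Some calls lay outside the comparisons above, in transcript probe sets to which the annotation used here gives no gene symbol. When every transcript probe set was tested with limma, 1020 of 22206 passed the adjusted p threshold of 0.05. Of the 2634 with no symbol 68 passed, a smaller share. Of these 68, 29 were higher in the knockdown than in the controls and 39 were lower, and 8 differed at least 2-fold, with log2 differences between -1.89 and 1.52. Which genes they measure was not determined. With 3 arrays per group, single arrays were not tested as outliers.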

How the results depend on the processing

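The fits without both control replicate 3 and knockdown replicate 5 were chosen after seeing the data. Rras2 kept its direction in every setting, from -1.29 to -1.59, and its adjusted p lay between 9.76e-05 and 0.0131 except with the Welch test per gene (-1.41, adjusted p = 0.253). That test called 0 genes, hence 0 higher, 0 lower and 0 changed at least 2-fold, with 2697 at an unadjusted p under 0.05; each gene then has its own spread from 3 arrays a group. eBayes with a trend and robust settings called 1908 genes (965 higher, 943 lower). Treat with a minimum fold of 1.2 called 182 (142 higher, 40 lower), since it tests against a larger change. Without 1 array the counts ranged from 392 to 1136 genes, 280 to 684 higher and 112 to 452 lower, and the 2-fold count from 108 to 191. Of the 135 genes changed at least 2-fold in the main fit, 112 kept their direction and stayed past the adjusted p threshold in all 6 fits. The 2-fold limit was not applied again for that count. Without both replicates named above, 203 genes were lower, and 681 passed in all. The cause of the larger count with the trend was not tested. Scalings gave 990 to 1073 genes, with 62.3% higher by cyclic loess, 57.4% as reported and 47.2% after median centring. All 1017 calls that were tested kept their sign in every setting. The calls came from these same arrays, and the Welch, treat and trend settings reuse the same log2 differences. The kept signs are therefore largely built in. Camera with an estimated correlation called 0 lists; the other settings called 22 to 28, losing the fibroblast and pericyte lists on ranks, the interferon, class I and pericyte lists with fry and the adipocyte list without both replicates named above, and 18 of the 24 lists passed in all 6 fits without 1 array. Ccl2, which had no difference, was -0.00696 after a second quantile normalization, -0.0398 after median centring and, without 1 array, ranged from -0.0839 (knockdown replicate 6) to 0.104 (knockdown replicate 5), with -0.0542 and -0.0179 without control replicate 3 and knockdown replicate 4. Mmp3 ranged from -0.0116 (control replicate 3) to 0.168 (control replicate 2), with -2.996e-05 without knockdown replicate 6; neither gene passed in any setting. The naming rule took 108 genes past the threshold, some of them from the list not described here, and 56 stayed in all 6 fits without 1 array. Myc and Cdkn1a passed with the trend (adjusted p = 0.0498 and 0.0451, the lowest of their alternatives, the highest being 1.00 with treat for both). Signal over background limits the dim genes: 8131 of 19505 lay above the 95th percentile of the negative controls.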

Other observations

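The genes named in the next 2 paragraphs, the comparison of single knockdown arrays, the reporter controls, and the tests of shared myosin sequence, of exit from the cell cycle and of knockdown replicate 5 in the interferon list were chosen after the results were seen. Several genes outside the lists changed as much as those within them. Igfbp2, a binding protein of the insulin-like growth factors, rose 5.69-fold. Igfbp5 passed too, but both its group means lay below the 95th percentile of the negative controls and it stayed in 1 of the 6 fits without 1 array (adjusted p up to 0.137). The muscle genes Myl4, Tnnc1 and Tnni1 rose 3.49-fold, 3.35-fold and 3.61-fold, with Tnni1 past in 4 of the 6 fits without 1 array (adjusted p up to 0.0569), and Mef2c, a transcription factor of muscle and neural cells, rose by 1.52 ± 0.09 (SE). Stmn2, a neuronal microtubule regulator, rose from 8.38 ± 0.16 to 10.63 ± 0.09 (SD, n = 3 each), and Gas6 rose 4.36-fold and Rgs4 3.50-fold. The control means of Tnnc1, Tnni1, Mef2c, Gas6 and Rgs4 lay below that percentile, so the sizes of these rises are imprecise. The neurofilament genes Nefm and Nefl fell by 1.76 and 1.18, with both group means of Nefl below that percentile, while Nefh differed by 0.01 ± 0.08. The near-identical paralogs Prl2c2, Prl2c3 and Prl2c5 fell by 1.84, 1.57 and 1.42, and their separate values are uncertain. Both group means of Prl2c5 lay below that percentile too, so the size of its fall is imprecise. Of the Zscan4 paralogs, all near background, Zscan4b and Zscan4f differed by -1.55 and -1.58 and passed, the second in 2 of the 6 fits without 1 array (adjusted p up to 0.151), while Zscan4a, Zscan4c and Zscan4d did not pass (adjusted p = 0.212, 0.288 and 0.143). When genes were grouped by the stem of their symbol, none of 1226 tests passed after adjustment; the lowest adjusted p was 0.068, shared by Adamts (5 of 18 higher), Polr (5 of 25 lower), Etv (3 of 6 lower) and Myl (4 of 11 higher).

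Knockdown replicate 5 had the weakest fall of Rras2, and other genes moved less on it too. For each knockdown array, genes were called from the other 5 arrays, and its deviation from the control mean was divided by that of the 2 other knockdown arrays. The median ratio was 1.11 over 392 genes for replicate 4, 0.66 over 1136 genes for replicate 5 and 1.00 over 431 genes for replicate 6, and the ratio for Rras2 itself was 1.28, 0.66 and 1.13. The median ratios rest on different genes, called with the arrays in the divisor, which can lower a ratio. For replicates 4 and 6 the divisor includes replicate 5, which can raise a ratio, so the values cannot be compared directly. On replicate 5, 1072 of the 1136 genes moved in the same direction as on the others. Whether this follows the amount of Rras2 cannot be tested with 3 arrays. Among 246 reporter control probe sets, 9 had mean signals of 9.55 to 9.77 against a median of 4.72 for the rest. These bright probe sets differed by 0.23 to 0.30 between groups, with no limma adjusted p below 0.135. Of all 246, 9 had an unadjusted p under 0.05 in limma. Whether those are the bright probe sets was not recorded.

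The rise of skeletal muscle genes was set against 3 explanations. Sequence shared among myosin heavy chains is argued against, since the 17 list members outside that family had a median log2 difference of 0.57 and 8 of them rose; 1 of the 21 members, Des, is in another list too. Exit from the cell cycle stays open. The mitosis list, with a median of 0.0433 (95% bootstrap interval 0.0184 to 0.0697), goes against it. The S phase and E2F list, with 40 of 42 members below 0 and a median of -0.16, and the fall of Mcm6 (-0.79) run with it. The bootstrap intervals here and in the next sentence resampled genes, not arrays, so they do not measure the spread between arrays. RNA of mature skeletal muscle stays open as well: 16 mature muscle genes outside the list, 3 of them above the 95th percentile of the negative controls in the control arrays, had a median of 0.60 (interval 0.28 to 0.73) and 7 rose, while the abundant muscle transcripts Ckm, Tcap and Actn3 differed by 0.15, 0.11 and -0.05; the bound set beforehand, 1.16, came only from members that had passed and was too high, and 0.68, the median of all 21 members, lies within the interval. Ckm and Tcap lay below the 95th percentile of the negative controls in both groups, so a change in them could be missed. A differentiation response to lower Rras2 is a candidate explanation that these arrays do not separate from other muscle-lineage cells, or from effects of the single shRNA on other targets, which were not tested.

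The interferon list passed camera at the preset correlation, though not with an estimated correlation (adjusted p = 0.629) or by fry (0.588), while 0 of its 44 members passed alone, with 8 at an unadjusted p under 0.05 in limma, 2 past the threshold with a trend and robust settings and 1 with array weights. Noise common to genes of like signal is argued against, since the list's median within-group SD was 0.53 and the highest among 10000 random lists matched on mean signal was 0.15. Without knockdown replicate 5, 14 members passed, and without both it and control replicate 3, 22; since these arrays were picked for their low values in this list, the counts decide nothing about the cause. What made control replicate 3 and knockdown replicate 5 lower than the others of their groups was not tested, and a biological effect of the knockdown stays open.

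The 6 arrays can be split into 2 groups of 3 in 10 ways, so a share under 0.05 cannot be reached. Every other split mixes controls and knockdown arrays in both groups, so a true difference widens the spread within them. Low counts there are therefore partly built in. For the genes past the threshold, 1 of the 10 splits, the real one, gave a count as large as 1017, and the highest of the other splits was 0. At an unadjusted p under 0.05 in limma, the real split had 3733 genes and the others up to 1283. For the genes changed at least 2-fold the real value was 135, reached by 1 split, and the highest other 0. For gene lists the real value was 24, reached by 1 split, and the highest other 12.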
